A study of Homo sapiens with 5 samples.

How the data were processed

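The series holds 5 Illumina BeadArray measurements of RNA from HEK293T cells, a human embryonic kidney line that carries the large T antigen. Per the labels' protocols, 200 pmol of a synthetic biotin-labelled microRNA duplex was transfected, cells were harvested 24 h later, and the microRNA with its bound transcripts was isolated on streptavidin beads before RNA extraction. Samples were grouped by their labels into 2 miR-182 pull-down arrays and 3 mock arrays. The mock arrays carry the value "none" in their pull-down field, although the same bead protocol is attached to them. Whether mock RNA passed over beads is therefore unsettled, and a difference between the groups can reflect the bead isolation, the microRNA, or both. The labels do not say that arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

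The values used were the log2 values in the table the authors deposited for the 5 arrays, with 11184 probes. The deposited log2 values ran from about 8 to 15.2, and the base of the logarithm was inferred from this range because the sources used here do not state it. Medians were 8.80 and 8.81 in pull-down arrays 1 and 2, and 8.79, 8.72 and 8.78 in mock arrays 1, 2 and 3. The submitters' processing notes list lumi 2.2.1 with no role. The background correction, transformation, normalization and probe filter are not given in the sources used here, so centring across arrays and the origin of the lower limit near 8 stay unknown. That lower limit compresses differences of dim probes. Between 14.9% and 26.7% of probes per array lay within 0.1 of the array's lowest value, and the pull-down arrays had the smaller shares. A second table of unnormalized signals with 39408 rows was not used, because none of its 10 columns of values (5 of signal and 5 of detection p-values) carries a name that matches a sample label. The design fixed beforehand assumed those signals and a detection filter. The deposited log2 values took their place, with no further normalization and no filter, and the test was otherwise kept.

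Probes were named through a platform annotation table, with symbols updated by Entrez identifier. Of the 11184 probes, 10040 had 1 symbol, 1 had several and 1143 had none; 10039 of the symbols were matched to a current gene record and 1 was kept as given. Probes with several symbols or none were left out of the gene tests. For each of the 8127 genes, the probe with the highest mean over the 5 arrays stood for the gene, and 6464 genes had a single probe. Gene symbols and Entrez identifiers follow the annotation, and no genome position is printed. Current symbols and the genomic span of each gene (introns included, used only as a property in the closing checks) came from a RefSeq gene table of the human assembly GRCh38.p14; the arrays name no assembly. Among 1663 genes with at least 2 probes, the difference of the chosen probe and that of the next one correlated across genes with r = 0.702.

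Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, group as the only term, all 5 arrays), and p-values were adjusted by the Benjamini-Hochberg method over the 8127 genes. A gene was called higher or lower at an adjusted p under 0.05. The fit had 3 residual degrees of freedom per gene and a prior of 1.61 degrees of freedom. Folds are 2 to the power of the log2 difference. With 2 arrays against 3 there are 10 ways to split the arrays, and an exact permutation test of a single gene could not fall below p = 0.1. The number of arrays limits the precision. The fit was also run on simulated data with the spread of these arrays. It recovered 17 of 67 genes changed by 0.5 in log2, 59 of 67 changed by 1 and 66 of 66 changed by 2. Among 150 genes called there, 8 were unchanged, out of 8127 genes simulated. Far fewer genes were changed there than the 2855 called in the data, which makes the adjusted threshold stricter, and noise was independent between genes. These shares therefore do not carry over directly to the data.

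Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists were tested against all other genes with limma's camera (preset correlation 0.01 between genes), with Benjamini-Hochberg adjustment over the 28 lists with enough members. They were tested again with an estimated correlation. In that second mode camera also falls back on the 3 residual degrees of freedom, so few lists can pass after adjustment. Limma's fry was run as well. It asks whether the members of a list move on balance 1 way and makes no comparison with other genes. The share of DNA repair and checkpoint genes among the called genes was tested with Fisher's exact test. The genes named are the 10 largest called differences in each direction with non-overlapping arrays, genes fixed in advance (among them FOXO1, FOXO3, BRCA1, CHEK2, RAD17, SESN2 and MTSS1), and up to 3 members of each described list with the smallest p. The ranking by size left out symbols that start with LOC, HS. or KIAA. SESN2 had no probe among the values used and was not analysed here, and a further gene fixed in advance is not reported here. Of the list members that the rule gives, the text prints some, since 28 of the 88 called genes it covers lost their call when 1 array was left out.

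The alternatives tried were the mean of all probes of a gene, eBayes with trend and robust estimation, array weights, the replicate number as a block, leaving out each array, and a 2-fold size threshold. Added after the data were seen were quantile normalization, median scaling and cyclic loess of the deposited values, and a restriction to genes with a mean log2 value of at least 9. A test of miR-182-5p seed sites was not run, because no 3′ UTR sequences were used here.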

Results

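RNA from HEK293T cells was measured on 5 Illumina expression BeadArrays, 2 from cells given biotin-labelled miR-182-5p and isolated on streptavidin (the miR-182 pull-down) and 3 from mock-transfected cells. A biotin pull-down recovers a tagged microRNA together with the transcripts bound to it, so a transcript held by the microRNA should have a higher signal after the pull-down. The mock arrays are labelled with no pull-down, so the bead isolation and the microRNA are not separated in this comparison. The comparison addresses which transcripts associate with miR-182, and the title of the series names DNA repair. Replicate arrays correlated with r = 0.978 in the pull-down and 0.980 to 0.987 in the mock across probes, and arrays of different groups with r = 0.885 to 0.904. Genes are not independent replicates in these correlations. All differences are pull-down minus mock on the scale of the authors' deposited log2 values, and levels are given as mean ± SD with n = 2 pull-down and n = 3 mock arrays.

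Rankings of the largest differences, here and below, cover called genes and leave out symbols that start with LOC, HS. or KIAA. The gene with the largest positive difference so ranked was KLHL8, an adaptor of cullin ubiquitin ligases. It was at 11.96 ± 0.08 in the miR-182 pull-down against 8.81 ± 0.10 in the mock, a log2 difference of 3.15 (SE 0.09) or 8.85-fold. HDAC3, a histone deacetylase of nuclear corepressor complexes, was higher by 2.59 (SE 0.08), and MED24, a Mediator subunit, by 2.49 (SE 0.13). At the other end, RPL7A, a protein of the large ribosomal subunit, was at 9.10 ± 0.02 in the pull-down against 12.54 ± 0.11 in the mock, a log2 difference of -3.44 (SE 0.09). In all, 1640 of 8127 genes (20.2%) were higher and 1215 (15.0%) lower in the pull-down by limma at a Benjamini-Hochberg adjusted p under 0.05, and 429 and 416 of these differed at least 2-fold.

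Besides KLHL8, HDAC3 and MED24, the 10 largest positive differences were those of RTL8A (3.00, SE 0.33), RIDA (2.51, SE 0.19), the endosomal GTPase RAB5A (2.35, SE 0.18), the mRNA export factor THOC3 (2.25, SE 0.15), the coatomer subunit COPG2 (2.24, SE 0.28), the kinase PRKCQ (4.58-fold) and the ubiquinone biosynthesis enzyme COQ6 (2.08, SE 0.12). Adjusted p-values of these 10 genes lay between 0.00163 and 0.00755 (limma, Benjamini-Hochberg). Further probes gave 2.87 for KLHL8, 2.27 for MED24 and 1.41 for RIDA. The second RTL8A probe gave 0.99, and RTL8A has near-identical paralogs that its probe can share, so its value is uncertain. The mock level of PRKCQ, 8.06 ± 0.02, was at the lower limit of the values, and its difference is compressed.

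After RPL7A, the largest negative differences were those of the mitochondrial ribosomal protein gene MRPL36 (-2.29, SE 0.12), NFATC2IP (-2.27, SE 0.07), the neuronal ubiquitin hydrolase gene UCHL1 (-2.24, SE 0.08), the signal peptidase subunit SEC11C (-2.24, SE 0.11), the cytochrome oxidase subunit COX7B (-2.23, SE 0.20), the esterase ESD (-2.18, SE 0.10), MRPL13 (-2.18, SE 0.12) and the ribosomal protein genes RPL7 (-2.13, SE 0.17) and RPL13A (-2.05, SE 0.20). Limma's Benjamini-Hochberg adjusted p-values of the 10 ranged from 0.00163 to 0.0049. Other probes differed for NFATC2IP (-0.09 and -0.03) and ESD (-0.40), so these values rest on 1 probe each. The other genes of this negative set, RPL7A included, had only 1 probe, as did HDAC3, RAB5A, THOC3, COPG2, PRKCQ and COQ6. Ribosomal protein genes have many processed pseudogenes, and their probes can share signal with them. None of the 20 genes named up to here lost its call in any alternative that tested it. They were picked as the largest calls on these same arrays, so this is not separate evidence for them.

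**Figure D1:**
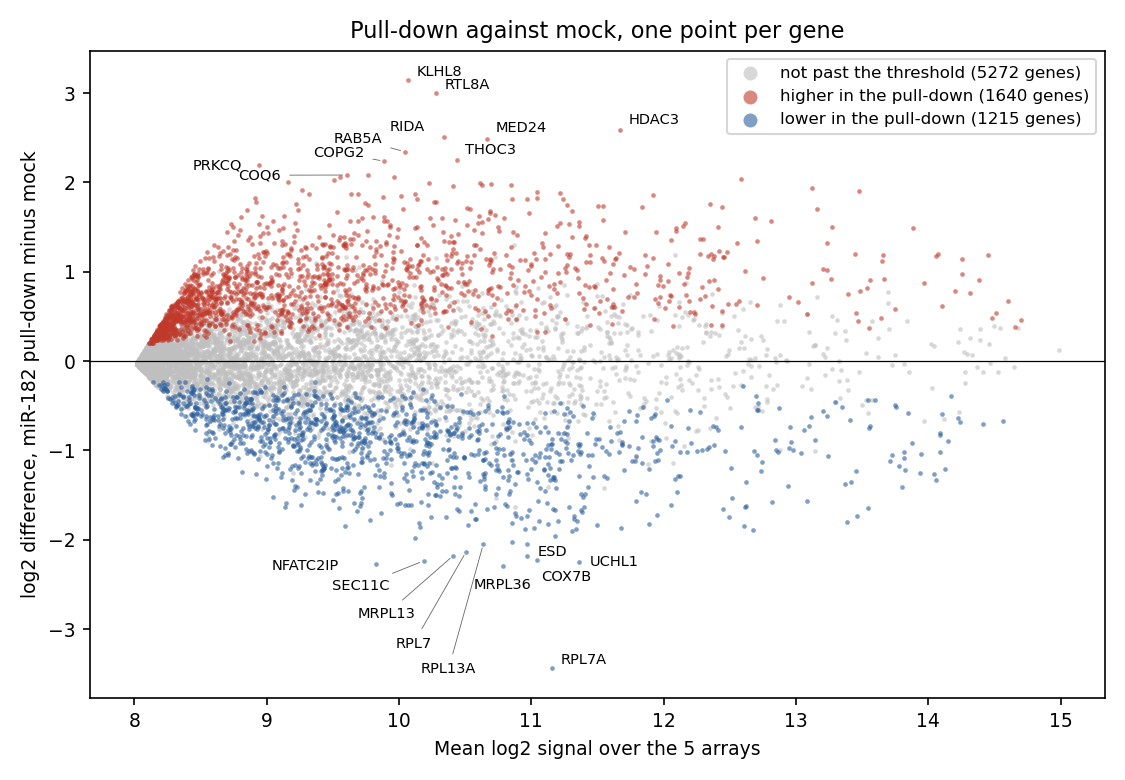
Each point is a gene, with its mean log2 signal over the 5 arrays on the horizontal axis and the log2 difference, miR-182 pull-down minus mock, on the vertical axis. Red marks the 1640 genes called higher, blue the 1215 called lower and grey the rest. The 10 largest called differences in each direction, leaving out symbols that start with LOC, HS. or KIAA, are named, from 3.15 for KLHL8 to -3.44 for RPL7A. The wedge at the left shows how the lower limit of the values compresses dim genes.

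Among genes of DNA repair and the damage checkpoint, BARD1, the RING partner of BRCA1, had the largest difference, with 11.01 ± 0.20 in the pull-down against 8.94 ± 0.11 in the mock (log2 difference 2.08, SE 0.12, limma, Benjamini-Hochberg adjusted p = 0.00281). MSH3, a mismatch recognition protein, was 3.58-fold higher, BABAM1, a subunit of the BRCA1-A complex, 2.70-fold and ERCC3, a helicase of TFIIH, 2.49-fold. GADD45A and the cell cycle inhibitor CDKN1A, both induced by p53, were 2.44-fold and 2.35-fold higher. RPA3, the smallest subunit of the single-strand binding protein RPA, went the other way, with a log2 difference of -1.60 (SE 0.13). Of 100 measured members of the list of all repair and checkpoint genes, 23 were higher, 10 lower and 67 not past the threshold, and 23 and 9 when adjusted over the list alone. Without mock array 2 there were 14 higher calls in the list, and without pull-down array 1 there were 3 lower calls.

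As a whole the list did not pass the test against other genes, with a median difference of 0.02 and a mean of 0.10 (limma's camera, Benjamini-Hochberg adjusted p = 0.857), and its median was below 0 under each of the 3 other scalings tried. Higher calls made up 23.0% of the repair list and 20.1% of the 8027 other genes, an odds ratio of 1.18 with a 95% confidence interval of 0.707 to 1.91 (2-sided Fisher's exact test, p = 0.454). At a difference of at least 2-fold, 10 of the 100 repair genes were higher, against 5.22% of other genes. That odds ratio was 2.02 (0.929 to 3.92), with p = 0.0419 by Fisher's exact test and 0.126 after Benjamini-Hochberg adjustment over 3 such tests. Lower calls numbered 10 of 100 against 15.0% elsewhere, an odds ratio of 0.629 (Fisher's exact test, p = 0.203).

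BRCA1, a central protein of homologous recombination, was 2.03-fold higher at 10.20 ± 0.21 against 9.18 ± 0.24 (log2 difference 1.02, SE 0.18, limma, Benjamini-Hochberg adjusted p = 0.0159), and its other probe gave 1.35. Its adjusted p was 0.0752 without pull-down array 2 and 0.0585 without mock array 2 (limma, Benjamini-Hochberg). CHEK2, a checkpoint kinase, was 1.87-fold higher (log2 difference 0.90, SE 0.15), with 1.15 at its other probe. RAD17, a checkpoint clamp loader, was higher by 0.93 (SE 0.07), with a mock level of 8.07 ± 0.03 at the lower limit.

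FOXO3, a stress-responsive transcription factor and reported miR-182 target, was 2.43-fold higher (log2 difference 1.28, SE 0.20, limma, Benjamini-Hochberg adjusted p = 0.0120), with 0.71 at its other probe. Without pull-down array 1 its difference was 1.16 with an adjusted p of 0.0680 (limma, Benjamini-Hochberg). The related FOXO1 was 1.33-fold higher (0.41, SE 0.10, limma, Benjamini-Hochberg adjusted p = 0.0347), a call that ended when pull-down array 1 (adjusted p = 0.139), pull-down array 2 (0.111), mock array 1 (0.0852) or mock array 2 (0.0517) was left out, and under each of the 3 other scalings. MTSS1, a cytoskeletal scaffold, had a difference of 0.03 (SE 0.05, limma, Benjamini-Hochberg adjusted p = 0.746). Its mock level of 8.07 ± 0.03 was at the lower limit and its pull-down level of 8.10 ± 0.01 just above it. A difference is compressed at such levels, so this value does not decide whether MTSS1 was enriched.

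**Figure D2:**
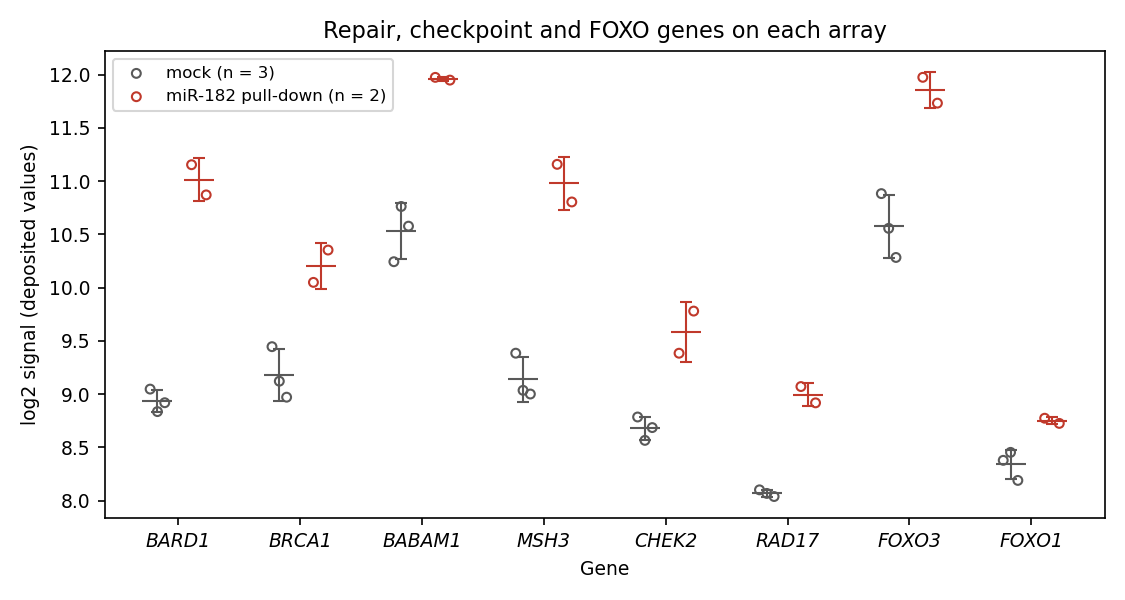
Open circles are single arrays (grey mock, n = 3; red miR-182 pull-down, n = 2), horizontal bars are group means and error bars 1 SD, on the log2 scale of the deposited values. The 8 genes were all called higher, and every called gene had non-overlapping arrays, so both pull-down arrays lie above all 3 mock arrays by that choice. Differences run from 0.41 for FOXO1 to 2.08 for BARD1. The 10 lower repair and checkpoint genes, RPA3 (-1.60) among them, and the uncalled MTSS1 are not shown.

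By pathway, 8 of 27 homologous recombination genes were higher and 3 lower (8 and 3 adjusted over the list alone), with BARD1, BABAM1 and RPA3 as above and a median of 0.29 (limma's camera, Benjamini-Hochberg adjusted p = 0.338). Nucleotide excision repair had 5 of 19 members higher and none lower. Besides ERCC3 these included the TFIIH subunits GTF2H5 (0.83, SE 0.12) and CDK7 (0.86, SE 0.13), and the list median was 0.02 (limma's camera, Benjamini-Hochberg adjusted p = 0.734). Fanconi anaemia genes had 3 of 10 members higher and 0 lower, with a median of 0.31 (limma's camera, Benjamini-Hochberg adjusted p = 0.502). The 3 were FAN1, FANCI and PALB2. The list had 0 higher calls without mock array 2 and 1 without mock array 1 or mock array 3. FAN1 and PALB2 lost their calls without pull-down array 1, and FANCI and PALB2 without pull-down array 2. Mismatch repair had 2 of 8 members higher, MSH3 among them, and 1 lower, and its median of -0.01 and mean of 0.20 differed in sign (limma's camera, Benjamini-Hochberg adjusted p = 0.962). Of 8 end-joining genes 2 were higher and 1 lower, with a median of 0.05 (limma's camera, Benjamini-Hochberg adjusted p = 0.906). These were RIF1 and TP53BP1, higher, and XRCC5, lower. None of the 8 was called without pull-down array 1 or mock array 1, 0 were higher without pull-down array 2 or mock array 3, and TP53BP1 lost its call with any of the 5 arrays left out. The damage checkpoint list had 4 of 18 members higher, RAD17, GADD45A, CDKN1A and CHEK2, and 4 lower, with a median of -0.07 (limma's camera, Benjamini-Hochberg adjusted p = 0.857). Base excision repair had 0 of 16 members higher and 1 lower (0 and 0 adjusted over the list alone), with a median of -0.20 (limma's camera, Benjamini-Hochberg adjusted p = 0.273). Leaving out 1 array left 4 to 7 homologous recombination genes higher (4 without mock array 2) and 1 to 2 lower, 3 to 5 nucleotide excision repair genes higher (3 without pull-down array 1 or mock array 2), and 0 to 2 checkpoint genes lower (0 without pull-down array 1 or mock array 1). NTHL1, the 1 lower gene in base excision repair, lost its call without either pull-down array, mock array 2 or mock array 3. The list had 0 lower calls without mock array 2, and its 1 lower call without mock array 3 was another member. In mismatch repair, POLD1 and PCNA kept their direction but lost their calls with either pull-down array left out. The medians of nucleotide excision repair, end joining and mismatch repair changed sign under at least 1 other scaling.

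Cytosolic ribosomal protein genes were lower as a group. Of 66 members, 40 were lower and 9 higher (42 and 15 adjusted over the list alone), with a median of -0.69 and a mean of -0.59 (limma's camera, Benjamini-Hochberg adjusted p = 3.80e-06). With an estimated correlation the list had adjusted p = 0.322 (limma's camera, Benjamini-Hochberg). That estimate, 0.0075, was below the preset 0.01, so the larger p comes from the fewer degrees of freedom of this mode. RPL24 fell by 1.65 and RPS21 fell by 1.49, while RPS26, chosen after its values were seen, was higher by 1.51. The ribosomal list was the only one of 28 lists tested that passed with the preset correlation; 5 lists had an unadjusted camera p under 0.05, and none passed with an estimated correlation. By limma's fry, 6 lists passed, namely ribosomal proteins (Benjamini-Hochberg adjusted p = 0.00214), replication-dependent histones, ZNF genes, Fanconi anaemia, nucleotide excision repair and biotin-dependent enzymes.

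**Figure D3:**
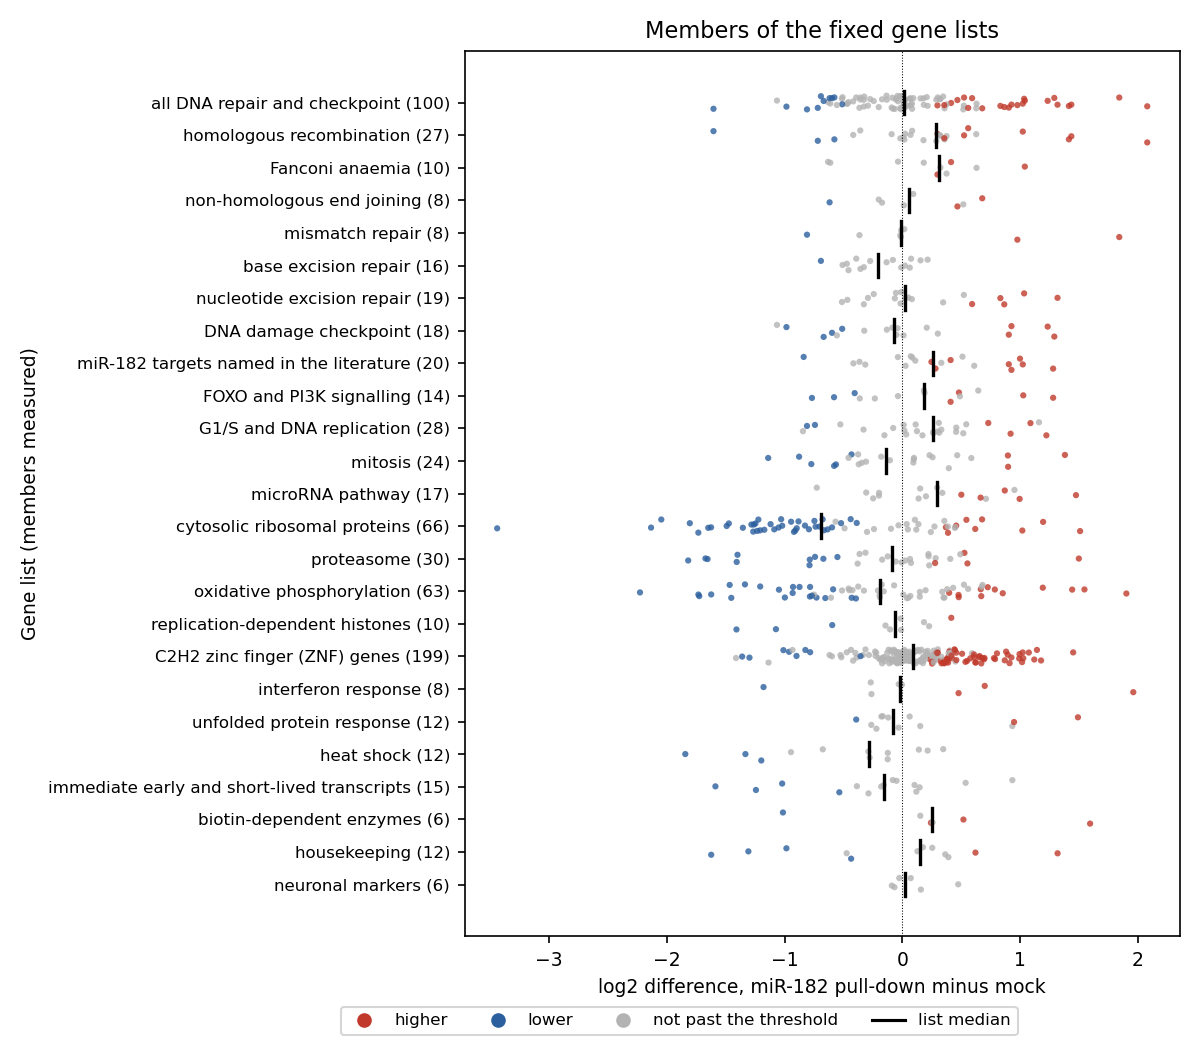
Each point is a measured member of a gene list fixed in advance, placed by its log2 difference, miR-182 pull-down minus mock; red, blue and grey mark higher, lower and uncalled members, black bars list medians, and numbers in parentheses the members measured. The ribosomal protein list has its median at -0.69, while the list of all repair and checkpoint genes, with 23 higher and 10 lower members, has its median at 0.02; the medians of 6 lists near 0 change sign under another scaling.

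Of 20 miR-182 targets named in the literature, 8 were higher, FOXO3, BRCA1, CHEK2, RAD17 and FOXO1 among them, and 1 was lower (9 and 1 adjusted over the list alone), with a median of 0.26 (limma's camera, Benjamini-Hochberg adjusted p = 0.273). That list was written from general knowledge and may hold genes picked in this very study, so it is not independent evidence. With an estimated correlation, 0.292 for this list, it had adjusted p = 0.843 on all arrays (limma's camera, Benjamini-Hochberg). That mode also has fewer degrees of freedom. Without pull-down array 2, which leaves 1 pull-down array, the median of the list was 0.33. The microRNA pathway list had 5 of 17 members higher and none lower, led by the Argonaute gene AGO1 (1.47, SE 0.09) and the decapping factor DCP1A (0.99, SE 0.15), with a median of 0.30 (limma's camera, Benjamini-Hochberg adjusted p = 0.289). FOXO and PI3K signalling had 4 of 14 members higher and 3 lower (7 and 4 adjusted over the list alone), and its median was 0.18 (limma's camera, Benjamini-Hochberg adjusted p = 0.857). The microRNA pathway had 1 lower call without mock array 3, and lower calls also arose there without pull-down array 1. Without mock array 2, 3 of the literature targets and 2 of the microRNA pathway were higher. Without pull-down array 1 these counts were 4 and 2, and FOXO and PI3K signalling had 0 higher calls.

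Among proliferation genes, 4 of 28 in the list of G1/S and DNA replication were higher, such as the kinase CDK6 (1.22, SE 0.13) and the transcription factor E2F3 (0.73, SE 0.10), and 2 were lower, among them thymidylate synthase TYMS (-0.74, SE 0.10; 2 and 2 adjusted over the list alone). In mitosis 3 of 24 were higher, led by the kinase AURKA (1.38, SE 0.08; 1.44 at its other probe), and 6 lower, including the cyclin CCNA2 (-0.77, SE 0.08). Proteasome genes had 4 of 30 members higher and 10 lower, with PSMA3 at -1.67 (SE 0.13), PSMA4 at -1.65 (SE 0.11) and PSMB1 at -1.40 (SE 0.10). In oxidative phosphorylation 12 of 63 were higher, COX4I1 at 1.19 (SE 0.08) among them, and 21 lower (15 and 23 adjusted over the list alone), with COX6A1 at -1.73 (SE 0.12) and NDUFB7 at -1.34 (SE 0.10). With 1 mock array left out, 1 to 3 mitosis genes were lower (1 without mock array 1) and 2 to 4 higher. In the proteasome 7 to 9 were lower and 1 to 3 higher. For oxidative phosphorylation these counts were 17 to 20 and 9 to 13, and 2 to 3 genes of G1/S and DNA replication were higher. Lower calls of the proteasome fell further without pull-down array 1, and those of oxidative phosphorylation without either pull-down array. None of these 4 lists passed limma's camera at the preset correlation, with Benjamini-Hochberg adjusted p from 0.273 to 0.569. Without pull-down array 2 the proteasome list passed (limma's camera, Benjamini-Hochberg adjusted p = 0.0246).

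The C2H2 zinc finger (ZNF) list had 57 of 199 members higher and 8 lower, with a median of 0.09 (limma's camera, Benjamini-Hochberg adjusted p = 0.204, and 0.0486 without pull-down array 2). Without pull-down array 1, pull-down array 2 or mock array 2, 28 were higher, and 3 to 10 were lower with 1 array left out. ZNF585A (1.12, SE 0.05) and ZNF211 (1.02, SE 0.06) were at the lower limit in the mock, and ZNF207 was lower (-1.30, SE 0.08). Of the 43 ZNF genes with a mean log2 value of at least 9, 10 were higher and 6 lower, and of the other 156, 47 were higher and 2 lower. In limma refitted to genes with such a mean alone, 8 of the 43 ZNF genes were higher and 12 lower, with a median of -0.04. Replication-dependent histones had 1 of 10 members higher and 3 lower, with H4C3 at -1.41 (SE 0.20). H1-2 was at 9.10 ± 0.02 in the mock and 8.02 ± 0.01 in the pull-down, at the lower limit, so that its difference of -1.07 (SE 0.05) is compressed. MYC, a short-lived transcription factor transcript, was lower (-1.59, SE 0.11), and the immediate early list had 0 of 15 members higher and 4 lower (0 and 3 adjusted over the list alone), and 1 lower with either pull-down array left out. Heat shock genes had 0 of 12 members higher and 3 lower (0 and 0 adjusted over the list alone), with HSPA8 at 11.50 ± 1.05 against 13.34 ± 0.20, and the list passed only without pull-down array 2 (limma's camera, Benjamini-Hochberg adjusted p = 0.00673, median -0.84). Its median was -0.28 with all arrays and 0.07 without pull-down array 1. HSPA8 itself lost its call without mock array 1 (adjusted p = 0.111), mock array 2 (0.0944) or mock array 3 (0.0910; limma, Benjamini-Hochberg), and the list had no call without mock array 1 or mock array 2.

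In the interferon response list 3 of 8 members were higher, with the RNA-activated kinase EIF2AK2 at 1.96 (SE 0.29), and 1 was lower (3 and 3 adjusted over the list alone). In the unfolded protein response 2 of 12 were higher and 1 lower (2 and 0 adjusted over the list alone). The lower gene, XBP1, lost its call with any array left out, and 1 member was higher without mock array 2. The transcription factor ATF4 had a difference of 1.49 (SE 0.13), and of its 2 other probes 1 gave -0.08 and 1 a larger positive difference. Of 3 measured members of the list named nuclear non-coding RNAs, SNHG5 was lower (-1.63, SE 0.17), 1 was higher and 1 uncalled. Where these RNAs lie in the cell was not measured. Biotin-dependent enzymes, whose proteins carry biotin themselves, had 3 of 6 members higher and 1 lower (5 and 1 adjusted over the list alone), and 0 called without mock array 2. Of 12 housekeeping genes, TBP (0.62, SE 0.07) and YWHAZ (1.32, SE 0.20) were higher and 4 lower, among them GUSB (-0.98, SE 0.10). Adjusted over the list alone these were 2 and 5, and without mock array 1 or mock array 2 they were 2 and 2. Medians and means differed in sign for housekeeping genes (0.15 and -0.13), the interferon response (-0.02 and 0.17) and the unfolded protein response (-0.08 and 0.18). In the marker lists of other cell types fixed in advance, which do not hold UCHL1, no member was called, with 0 of 2 blood, 0 of 1 fibroblast, 0 of 2 epithelial and 0 of 6 neuronal genes past limma's threshold and 1 of these, ENO2 (0.47, SE 0.17), at an unadjusted p under 0.05. ENO2 was called higher without mock array 3 (0.60, limma, Benjamini-Hochberg adjusted p = 0.0446). The markers HBA2, COL1A1, KRT18 and SYP were at the lower limit in both groups. With so few markers measured above it, the absence of calls says little about RNA of other cell types. None of these lists passed limma's camera after Benjamini-Hochberg adjustment. For lists with no such count beside them, the calls adjusted over the list alone were as many as those over all genes.

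All 2855 called genes had non-overlapping arrays, as did 5291 of all genes (65.1%), where chance gives 20%. Of the higher genes, 334 had a mock level within 0.1 of the lower limit, and of the called genes with a mean log2 value of at least 9, 823 were higher and 953 lower. Leaving out pull-down array 1 left 958 higher and 638 lower calls, leaving out pull-down array 2 left 674 lower calls, and leaving out mock array 2 left 989 higher calls.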

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

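Probes without a gene name in the annotation used here entered no comparison of the report, and some of them differed between the groups. Of these 1143 probes, 194 were higher and 153 lower in the miR-182 pull-down than in the mock when limma was fitted to all 11184 probes (Benjamini-Hochberg adjusted p under 0.05), with both pull-down arrays outside the range of the 3 mock arrays in each direction. The largest positive difference among them was 1.69 on the log2 scale. Over all probes of that fit, 2142 were higher and 1584 lower.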

How the results depend on the processing

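Quantile normalization, median scaling, cyclic loess and the restriction to a mean log2 value of at least 9 were chosen after the data were seen. Alternatives fixed in advance that need unnormalized signals or detection p-values (other background corrections, offsets, scalings of raw signals, detection filters and a slide block) were not run. With array 1 of the pull-down, or array 2, left out, the lone pull-down array is assumed to vary like the mock. Leaving out 1 array gave 958 to 1379 genes higher (958 without pull-down array 1, 989 without mock array 2), 638 to 1205 lower (638 and 674 without pull-down arrays 1 and 2), 349 to 434 and 317 to 445 at least 2-fold, and 1 to 5 gene lists past the threshold. The 5 lists without pull-down array 2 were ribosomal proteins, heat shock, proteasome, literature targets and ZNF genes, and the cause was not tested. Refitted to the 3831 genes with a mean log2 value of at least 9 alone, limma called 954 higher and 1116 lower, with its prior and adjustment taken from these genes (46.1% of calls higher, against 57.4% of all). With an estimated correlation, which leaves camera fewer degrees of freedom, 0 gene lists passed. Cytosolic ribosomal proteins (median -0.69) had limma's camera adjusted p = 0.322 there after Benjamini-Hochberg adjustment. In the 13 other alternatives that list kept a median of -0.75 to -0.61 and a camera adjusted p of 5.72e-07 to 2.38e-04. DNA repair genes had an odds ratio of 2.02 among genes at least 2-fold higher (Fisher's exact test, p = 0.0419), with 1.53 to 2.69 in 13 alternatives and p under 0.05 in 3 of them. The ratio among all higher genes was 0.935 to 1.74 and never past the threshold, and the median of the repair list was -0.02 to 0.05. Of the 88 called genes that the naming rule covers, 59 kept their call in every alternative that tested them, 28 lost it when 1 array was left out, and none changed direction past the threshold.

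Replicate numbers 1 and 2 occur in both groups, and same-numbered arrays deviated together weakly (r = 0.0361 and 0.115 across genes). With 2 pull-down arrays their deviations mirror each other, so these are not separate checks. Nothing in the labels ties the arrays, so whether same-numbered arrays share a batch stays unsettled. Number 3 occurs only in the mock, so a block on the replicate number takes up mock array 3 entirely. Its estimates equal those without mock array 3, on fewer residual degrees of freedom than the main fit. Under this replicate block, 1289 genes were higher and 1132 lower, 426 and 439 of them at least 2-fold. There 1 gene list passed, the ribosomal median was -0.75, the repair median was -0.00 and the repair odds ratio was 0.935. Of the 88 named calls, 73 were kept and 15 were not made under this block, BRCA1, CHEK2 and FOXO1 among the latter. BRCA1, CHEK2 and FOXO1 were called with mock array 3 simply left out, so these losses do not show a shared batch. The lower limit near 8 keeps dim genes from showing their size.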

Other observations

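The scan of gene families, the trend with gene span, Fisher's exact tests of ZNF genes, their lower calls against matched lists, and their tests after cyclic loess and on either side of a mean log2 value of 9 were chosen only after results were seen. Among 81 families that share a symbol stem and have at least 10 members, a family of mitochondrial ribosomal proteins passed the test in the same direction as the cytosolic ones. Of 48 genes with the stem MRPL, for the large subunit of the mitochondrial ribosome, 21 were lower and 6 higher in the pull-down, with a median of -0.32 (limma's camera, Benjamini-Hochberg adjusted p = 0.0135, and adjusted p = 0.840 with an estimated correlation). The small-subunit MRPS genes had 11 lower and 5 higher of 28, a median of -0.53 and an adjusted p of 0.0824 (limma's camera, Benjamini-Hochberg).

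In the other direction, 10 of 27 genes with the stem USP, all but USP6NL ubiquitin-specific proteases, were higher and 1 lower, with a median of 0.31 that stayed between 0.26 and 0.31 under the other scalings (limma's camera, Benjamini-Hochberg adjusted p = 0.131). The KLHL family, to which KLHL8 belongs, had 6 of 18 members higher and 1 lower, with a median of 0.22 (limma's camera, Benjamini-Hochberg adjusted p = 0.139). Across 8126 genes the difference rose with the genomic span of the gene (Spearman's rho 0.220, genes not being independent), from a median of -0.11 in the shortest of 10 equal groups to 0.19 in the longest, and rho was 0.215 among the 3831 genes with a mean log2 value of at least 9.

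The lower signals of cytosolic ribosomal protein genes, with a median of -0.69, were set against 10000 random lists of equal size. Lists matched on mean signal had medians from -0.16 to 0.27 in 95% of draws, and lists matched on genomic span had medians from -0.20 to 0.00. The ribosomal median lay below both ranges, so neither property alone gave so low a median in randomly drawn genes. The draws took genes as independent and never matched both properties at once. They therefore do not exclude a part for signal level or gene span. Ribosomal genes spanned a median of 5.05 kb against 29.0 kb for all genes. Signal that ribosomal probes may share with pseudogenes was not tested, nor was any property other than signal and span. The mock itself also stays open, since 0 of the 3 mock arrays have a label that names a pull-down. A difference between bead-isolated and total RNA thus cannot be told apart from an effect of miR-182, and both may contribute.

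Of the 199 ZNF genes 57 (28.6%) were higher, against 1583 of 7928 other genes (Fisher's exact test, genes taken as independent, odds ratio 1.61, p = 0.00404), while the list did not pass limma's camera (Benjamini-Hochberg adjusted p = 0.204, and adjusted p = 0.843 with an estimated correlation). Without pull-down array 2 the share was 14.1%, as among all genes (14.1%), and without pull-down array 1 or mock array 2 it was 14.1% against 11.8% and 12.2%. With all arrays, random lists matched on signal held 27 to 47 higher calls in 95% of draws, and lists matched on span 27 to 48. These draws take genes as independent, while camera estimated a correlation of 0.032 among ZNF genes. Such a correlation widens the ranges, so they do not decide on signal or span as the cause of the count. After cyclic loess, which evens out dim and bright values, 46 ZNF genes were higher, against 23 to 42 in matched lists. The same limit applies, and loess cannot restore differences compressed at the lower limit, so the scaling of dim values stays open. Among dim genes (mean log2 value below 9) 47 of 156 ZNF genes were higher, an odds ratio of 1.89 (1.30 to 2.71), and among brighter genes 10 of 43, an odds ratio of 1.11 (0.485 to 2.32, Fisher's exact intervals), while limma refitted to the brighter genes alone called 8 of the 43 higher (18.6%, against 24.9% of all such genes); whether the dim and bright ratios differ was not tested.

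Lower calls were fewer among ZNF genes, 8 of 199 (4.02%) against 1207 of 7928 other genes (Fisher's exact test, genes taken as independent, odds ratio 0.233, p = 9.03e-07), and their share stayed below that of all genes with any 1 array left out, from 1.51% against 8.29% to 5.03% against 14.8%. Random lists matched on signal held 11 to 26 lower calls in 95% of draws, and lists matched on span 23 to 43. These draws too take genes as independent, so they do not decide on either as the cause of the low count. Median scaling gave 13 lower ZNF calls (6.53%, against 17.3% of all genes), and quantile normalization and cyclic loess gave 9 each. Lower calls were not set against matched lists under these scalings. Limma refitted to the brighter genes alone called 12 of the 43 lower (27.9%, against 29.1% of all such genes). For the higher and the lower calls of ZNF genes, signal level, gene span and the scaling of dim values remain candidate explanations. Recovery on the beads and binding by miR-182 remain so as well, and no test here separates them.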
